A study of Homo sapiens with 8 samples.

How the data were processed

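RNA sequencing was measured in 8 libraries of BT474-derived cells, with 2 libraries in each of 4 groups. BT474 is an established human breast carcinoma line with amplified ERBB2 and expressed estrogen receptor. The groups carry the names BT474T, HR6, HR6_Z8KO1 and HR6_Z8KO2 in the labels, and the first pair of groups shares a control knockout label. Per the labels' protocols, ZMYND8 guide RNAs were delivered by lentivirus with puromycin selection, cells were grown in RPMI medium with serum, RNA was column-purified with DNase treatment, and libraries were made with a poly-A mRNA kit. The labels do not say whether the libraries of a group came from separate cultures, so all p-values measure the spread between these libraries, which may be technical. The labels also leave open whether the knockout groups are clones or pools.

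The deposited table lists 19606 gene symbols with 3 values per library. The authors' first value is a whole-number read count per gene, without normalization. The second, per the file headers, is a CPM over an effective library size, handled here as a normalized coverage signal because its sums, from 983190 to 1034300, differed between libraries. The third is TPM as deposited by the authors, which corrects for gene length. Per the submitters' processing notes, FastQC 0.11.2, TopHat, Picard 1.127, featureCounts and edgeR were used with the hg19 build. The versions of TopHat, featureCounts and edgeR, the gene annotation and the strand setting are not given in the sources used here. Genes that share exons or near-identical copies, such as RPL7, HLA, histone, AKR1C and UGT1A genes, may therefore share or lose reads. Mitochondrially encoded genes were not analysed here.

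Library totals ran from 18452058 to 34711652 counts, and BT474T replicate 2 was the deepest. Within groups, the replicates correlated across genes at 0.997 or above on log2 values, and a chi-square test over genes found every pair to differ by more than sampling noise, with chi-square per gene from 1.27 to 3.17. Every library was therefore kept as 1 replicate. Counting intervals are exact binomial at 95% and, like the floor of 3 counts over a group, cover counting error only.

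Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), with TMM scaling. The filterByExpr filter kept 14585 genes, which held at least 99.957% of the counts of each library, and left out 5021. All 8 libraries entered 1 model with 4 group means and 4 residual degrees of freedom. The test for count data and for TPM had both been written down before the data were examined, and the count version was used. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were HR6 against BT474T, the mean of both knockout groups against HR6, each knockout group against HR6, and Z8KO2 against Z8KO1. Fold changes are log2 with the standard error (SE) derived from the test statistic. TPM means have the SD of 2 libraries.

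A gene with no count in a group has no fitted fold here. Its fold is given as at least the ratio to 3 counts over the group, and with 1 to 3 counts as a ratio with its counting interval. 35 gene lists were written before the data were examined. Of these, 31 had at least 5 tested members and were tested with camera (limma) at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry served as alternatives. Named genes followed a rule fixed beforehand. It takes ZMYND8, and the 10 highest and 10 lowest fold changes among called genes with a mean of at least 5 TPM in the higher group and no overlap between libraries. For the knockout comparison a call in the same direction in each knockout group was also required. It adds up to 4 called members of each list by size of change (or up to 2 uncalled where none was called), the 5 highest and 5 lowest between the knockout groups, and the 8 leading genes in each direction, by the product of both fitted log2 fold changes, among those moved the opposite way by both comparisons. ERBB2, EGFR, ERBB3, ESR1, PGR, IL27, MB21D1 (cGAS) and TMEM173 (STING) are named whatever their values. EBI3 had been picked with them but was not analysed here. Symbols starting with LOC, LINC, MIR, SNOR or RNU, clone names, symbols with -AS or -IT, XIST and Y-linked genes were left out of the ranked picks. Other uncharacterised or small RNA symbols, such as C1orf95 and RPPH1, were not.

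Tests were checked on simulated counts with 200 changed genes among 14585, in 5 simulations per comparison. For HR6 against BT474T, 63.6% of 1.25-fold, 79.6% of 1.5-fold, 89.2% of 2-fold and 98.4% of 4-fold changes were recovered, and 5.27% of calls were false. For the mean knockout comparison the shares were 61.2%, 79.6%, 86.8% and 98.4%, with 4.45% of calls false, and for Z8KO2 against Z8KO1 they were 56.4%, 72.8%, 88.4% and 97.6%, with 5.17% false. Camera called 5 of 5 planted lists and 0 of 100 unchanged lists in simulated counts of the knockout comparison. Every gene of a planted list was raised 1.5-fold and all other genes were unchanged. Smaller or mixed shifts within a list, and calls amid many changed genes, were therefore not checked. Genes were simulated independently, so neither check covers correlated genes, and the estimated correlation was 0.25 for ribosomal proteins in that comparison. Far more genes were called in the data, 10889 for HR6 against BT474T and 7111 for the mean knockout, than the 200 changed in the edgeR simulations. Because HR6 is shared by several comparisons, unchanged groups were simulated 20 times, with all libraries, those of HR6 included, drawn from the HR6 means. Gene order came from the RefSeq annotation of GRCh38.p14, used only for which genes neighbour each other, and 96.2% of symbols in the table had a place. A planted log2 shift of 1 in 100 neighbouring genes was recovered as 0.93 to 0.99 by the median of 30 neighbours among 13722 placed genes. Chromosome X was left out of these. GC content came from the GENCODE v29 transcripts and gene length from the ratio of the deposited counts to the deposited TPM. Both were available for 96.5% of tested genes.

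Alternatives fixed beforehand were DESeq2 1.42.0, median-ratio size factors, no filter, a mean of at least 5 TPM, a fold minimum, the compared groups alone, the replicate number as a block, each library left out in turn, and limma on log2(TPM + 0.1), log2(TPM + 5), quantile-normalized values, without trend and with robust variance. Added after the data were seen were limma on log2(TPM + 1), library size as the only scaling, thinning to the smallest total, removal of the GC and length trend, a crossed block, and a fit with each HR6 library as its own group, so that a pair of comparisons shares no HR6 library. The crossed block paired each BT474T library with the HR6 library of the other replicate number. Deviations of replicate 1 from its group mean correlated at -0.248 between BT474T and HR6, over 10163 genes. Between the other pairs of groups they correlated at -0.0363 to 0.0691, and the cause was not tested. Because these files hold counts, no recovery of whole reads was run.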

Results

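Messenger RNA was sequenced in trastuzumab-resistant and control cells derived from BT474, an ERBB2-amplified and estrogen receptor-positive breast carcinoma line. Trastuzumab is an antibody against the ERBB2 receptor. The groups were BT474T, HR6 (the resistant cells in which the knockouts were made), and the ZMYND8 knockout groups HR6_Z8KO1 and HR6_Z8KO2, here Z8KO1 and Z8KO2, with 2 libraries each. Total counts were 19300058 and 34711652 in BT474T, 20151034 and 20483455 in HR6, 19927351 and 21236710 in Z8KO1, and 18958583 and 18452058 in Z8KO2. The first principal component held 79.5% of the variance and separated BT474T from all HR6-derived libraries, and the second held 14.1% and separated HR6 from both knockout groups. The median biological coefficient of variation was 2.95%. All fold changes are from edgeR's quasi-likelihood fit, as log2 values with the SE, over 2 libraries per group.

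ZMYND8, a chromatin reader of histone marks and the targeted gene, was examined first. Its level was 271 and 263 TPM in the BT474T libraries and 271 and 258 TPM in the HR6 libraries. It was 123 and 126 TPM in Z8KO1 and 146 and 148 TPM in Z8KO2. Z8KO1 held 46.9% of the HR6 level (log2 fold change -1.09 ± 0.03) and Z8KO2 held 55.0% (-0.86 ± 0.03). Over both knockout groups the level was 50.8% of that in HR6, with an adjusted p of 1.8e-30 by edgeR's quasi-likelihood test. ZMYND8 mRNA therefore remained detectable in all 4 knockout libraries, and a count of whole-gene reads does not show whether these transcripts encode intact protein. HR6 and BT474T did not differ in ZMYND8 (0.06 ± 0.03, edgeR adjusted p = 0.081).

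**Figure D1:**
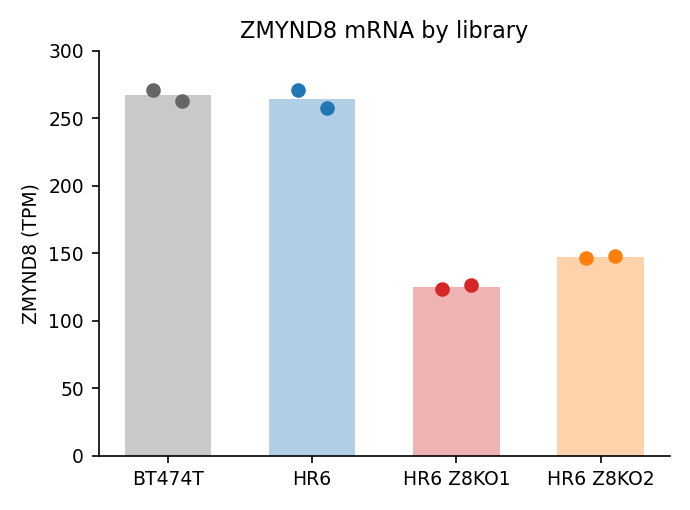
ZMYND8 in TPM (vertical axis, from 0) in each group (horizontal axis), with a bar at the mean of 2 libraries and a point for each library. The knockout libraries lie between 123 and 148 TPM and the BT474T and HR6 libraries between 258 and 271 TPM.

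The first comparison asked what separates the resistant HR6 cells from BT474T. HR6 had less of the hormone receptor mRNAs. Most tested members of the hypoxia list were lower and most of the antigen presentation and ribosomal protein lists higher, lists that camera called but not with an estimated correlation (adjusted p from 0.187 to 0.373). ESR1, the estrogen receptor, fell from a mean of 80.9 TPM to 21.0 ± 0.902 TPM (mean and SD; log2 fold change -1.87 ± 0.04), and PGR, the progesterone receptor, fell by 1.62 ± 0.08 on the log2 scale. ERBB2, the trastuzumab target, went from 4978 to 3841 TPM (-0.30 ± 0.03), EGFR changed by -0.91 ± 0.04 and ERBB3 by -0.49 ± 0.03. AZGP1, a secreted zinc-binding glycoprotein of apocrine cells, rose from 24.0 to 1228 TPM (5.76 ± 0.05). In all, 5460 genes were higher and 5429 lower in HR6 at an edgeR adjusted p under 0.05, of which 1402 and 1332 changed at least 2-fold. The share of calls that were higher was 50.1% here, 42.6% with limma on log2(TPM + 5) and 50.2% with limma on quantile-normalized values. Medians of 30 neighbours in gene order had an SD of 0.298 in this comparison and 0.0877 in the knockout comparison. Fold changes of single genes also spread more here (SD 1.33 against 0.639). Among the most extreme windows were those around RAD51C on chromosome 17 (-0.93) and MRPS15 on chromosome 1 (0.76). Whether calls between these lines follow chromosome segments was not tested.

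Several genes were read in only 1 of these lines. 7 genes with a mean of at least 5 TPM in HR6 had no count in BT474T, and 11 showed the opposite. ERN2, an endoplasmic reticulum stress sensor of mucosal epithelium, was at least 1535-fold higher in HR6 (64.9 TPM), the homeobox gene HOXB5 at least 216-fold, the aldo-keto reductase AKR1C2 at least 166-fold, MS4A15 at least 134-fold and C1orf110 at least 130-fold. AKR1C2 shares sequence with its neighbouring paralogs, so its reads could be divided among them. TIMP3, a metalloproteinase inhibitor, was 779-fold higher (counting interval 139 to 3.08e+04), the fucosyltransferase FUT6 717-fold (128 to 2.84e+04) and ARMCX3 262-fold (89.4 to 1.28e+03). CBLC, a ubiquitin ligase of receptor tyrosine kinases, rose by 8.25 ± 0.17 and C1orf95 by 7.80 ± 0.26. SIGLEC8, a sialic acid-binding lectin, was at least 891-fold lower in HR6, the snoRNA host gene SNHG6 at least 129-fold, the adaptor DOK5 at least 117-fold, PSG11 at least 51.7-fold, DKFZp434J0226 at least 44.9-fold and the inflammasome adaptor PYCARD at least 36.6-fold. The imprinted-locus transcript IPW was 1577-fold lower (counting interval 283 to 6.23e+04) and PAR5 at least 136-fold lower, and SNRPN, from the same locus, changed by -8.57 ± 0.14. GPX1, the main cytosolic glutathione peroxidase, fell from 176 to 0.399 TPM (-8.68 ± 0.17). SNRPN and SNURF share nearly all of their reads.

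Of the gene lists fixed beforehand, 9 of 31 passed camera in this comparison, and none did with an estimated correlation, where the lowest adjusted p was 0.187. Hypoxia and HIF-1 targets fell in 22 of 29 tested members and rose in 6, with a median of -1.02 (camera adjusted p = 8.3e-09; adjusted p = 0.187 with an estimated correlation). Among them were carbonic anhydrase CA9 (-4.51 ± 0.44), NDRG1 (-2.41 ± 0.04), adrenomedullin ADM (-2.38 ± 0.27) and the glycolytic ALDOC (-2.22 ± 0.11). Estrogen receptor targets were lower in 18 of 28 and higher in 8, or 9 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.187 with an estimated correlation). AGR3 was 289-fold lower (counting interval 79.7 to 2.39e+03), the chemokine CXCL12 changed by -5.31 ± 0.11 and the fatty acid elongase ELOVL2 by -2.01 ± 0.41, whereas carbonic anhydrase CA12 rose by 3.74 ± 0.06. Mitotic genes fell in 20 of 28 and rose in 1 (camera adjusted p = 0.0070; adjusted p = 0.373 with an estimated correlation), with the spindle genes DLGAP5 (-1.29 ± 0.07), HMMR (-1.21 ± 0.08), CENPE (-0.99 ± 0.07) and ASPM (-0.83 ± 0.05).

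Androgen response and apocrine genes were higher in 8 of 18 and lower in 5 (camera adjusted p = 2.2e-08; adjusted p = 0.187 with an estimated correlation). Beside AZGP1, the lipocalin APOD (5.33 ± 0.10) rose, and the acyl-CoA synthetase ACSM3 fell (-4.05 ± 0.15). Cytosolic ribosomal proteins rose in 23 of 27 and fell in 1 (median 0.53, camera adjusted p = 3.0e-10; adjusted p = 0.187 with an estimated correlation), with RPS2 at 1.49 ± 0.03, RPL7 at 1.19 ± 0.08 and RPL18 at 0.98 ± 0.03. Antigen presentation genes rose in 13 of 17 and fell in 3 (camera adjusted p = 0.026; adjusted p = 0.373 with an estimated correlation). HLA-F was at least 11-fold higher, the immunoproteasome subunit PSMB9 10.6-fold (counting interval 2.48 to 94.7) and PSMB8 rose by 4.03 ± 0.35. All of these stayed under 1 TPM in HR6, and HLA reads are divided among close paralogs. Acute-phase and secreted defence genes rose in 8 of 12 and fell in 2, or 3 adjusted over the list alone (median 3.64, or 2.32 with genes at 0 set to their bound; camera adjusted p = 0.026; adjusted p = 0.373 with an estimated correlation). The iron-siderophore binder LCN2 was 43.6-fold higher (counting interval 11.6 to 367), the protease inhibitor SLPI rose by 4.93 ± 0.22, complement factor CFB was 25.1-fold higher (3.99 to 1.04e+03) and the immunoglobulin receptor PIGR at least 1.76-fold.

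Other receptor tyrosine kinases and PI3K-AKT genes fell in 18 of 29 and rose in 10 (camera adjusted p = 0.037; adjusted p = 0.305 with an estimated correlation). The stem cell factor receptor KIT was 96.9-fold lower (counting interval 17.1 to 3.86e+03), and RET (-3.19 ± 0.07), the lipid phosphatase INPP4B (-2.83 ± 0.08) and the insulin receptor adaptor IRS1 (-2.35 ± 0.18) fell. Replication-dependent histones, whose mRNAs mostly lack poly-A tails, fell in 8 of 11 and rose in 1 (camera adjusted p = 0.021; adjusted p = 0.305 with an estimated correlation), with HIST1H2BD at -2.34 ± 0.09 and HIST1H1E at 1.86 ± 0.38. Camera on limma's log2(TPM + 1) values, a setting chosen after the data were seen, no longer called the receptor kinase, estrogen receptor, acute-phase, androgen response and histone lists, and on quantile-normalized values it lost the receptor kinase, acute-phase and androgen response lists. For 31 of 34 lists with tested members the counts were identical when adjusted over the list alone.

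Camera did not call the other 22 lists (adjusted p from 0.064 to 0.987), given here as genes higher and lower. These were DNA replication (22 and 7 of 35), unfolded protein and amino acid stress (15 and 10 of 27), interferon-stimulated genes (12 and 12 of 35), IL-6 family and JAK-STAT3 (11 and 4 of 19), p53 targets (10 and 8 of 24), ZMYND8 and its partners (9 and 16 of 31) and mesenchymal genes (9 and 8 of 23). Luminal identity had 8 and 9 of 22, stem cell markers 7 and 12 of 19, apoptosis regulators 7 and 10 of 22, cholesterol synthesis 6 and 14 of 24, fatty acid synthesis 5 and 13 of 20, drug efflux and mucins 5 and 8 of 14, NF-kB cytokines 5 and 5 of 12 (6 and 5 adjusted over the list alone), and oxysterol genes 5 and 6 of 13. Basal keratins had 4 and 3 of 10, DNA sensing 4 and 2 of 8, immediate early genes 4 and 9 of 16, genes next to ERBB2 3 and 9 of 13, ERBB receptors and ligands 3 and 5 of 8, endothelial markers 2 and 1 of 5, and packaging cell markers 2 and 3 of 5. Individual members still moved far. The antiviral synthetase OAS2 was at least 159-fold higher and OAS1 (5.67 ± 0.33), OAS3 (5.22 ± 0.15), TMEM173 (STING, 2.73 ± 0.12), the calprotectin subunit S100A9 (5.62 ± 0.33), CD44 (2.30 ± 0.05), PROM1 (3.31 ± 0.11), the ligands HBEGF (2.54 ± 0.42) and TGFA (1.47 ± 0.09), PPP1R1B (2.65 ± 0.03) and the drug transporter ABCC4 (3.45 ± 0.14) rose. N-cadherin CDH2 (-3.34 ± 0.16), PNMT (-3.25 ± 0.16), the cell cycle inhibitor CDKN1C (-3.51 ± 0.37), GATA3 (-2.02 ± 0.09), a luminal transcription factor, and the desaturase SCD (-1.46 ± 0.03) fell. Median and camera direction, or median and mean, differed in sign for the stem cell (median -0.24, mean -0.29, camera up), ERBB (median -0.39, mean 0.15, camera down), oxysterol (median -0.06, mean 0.10, camera down), luminal (median -0.04, mean 0.01, camera down) and apoptosis (median -0.03, mean 0.10, camera down) lists. Of lists with too few tested members for camera, the fibroblast genes COL6A3 (-1.58 ± 0.48) and COL1A1 (-0.51 ± 0.04) fell, the leukocyte genes CORO1A (2.11 ± 0.10) and CD68 (1.84 ± 0.28) rose with 2 of 4 not called, and the cancer-testis gene MAGEC1 was not called (-0.58 ± 0.71).

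The second comparison asked what the ZMYND8 knockout changed in HR6, taking the mean of both knockout groups. The knockout cells had less vimentin mRNA. Most tested members of the basal and secreted defence lists were higher and most of the cholesterol synthesis and ribosomal protein lists lower, lists that camera called but not with an estimated correlation (adjusted p from 0.0682 to 0.326). VIM, the intermediate filament of mesenchymal cells, fell from 29.1 ± 0.998 TPM (mean and SD) in HR6 to 2.09 and 2.02 TPM in Z8KO1 and Z8KO2 (-3.84 ± 0.11). TP63, the master transcription factor of squamous epithelium, rose from 0.433 to 8.52 and 10.2 TPM (4.41 ± 0.14), and LCN2 from 5.40 to 106 and 99.1 TPM (4.23 ± 0.12). The imprinted noncoding RNA H19 fell from 359 TPM to 41.9 and 38.1 TPM (-3.18 ± 0.04), near its 39.8 TPM in BT474T. At an edgeR adjusted p under 0.05, 3504 genes were higher and 3607 lower, of which 678 and 301 changed at least 2-fold. Which direction held more calls depended on the scaling, with 3960 higher and 3090 lower by library size alone, a setting chosen after the data were seen, and 2787 and 3391 with limma on quantile-normalized values.

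**Figure D2:**
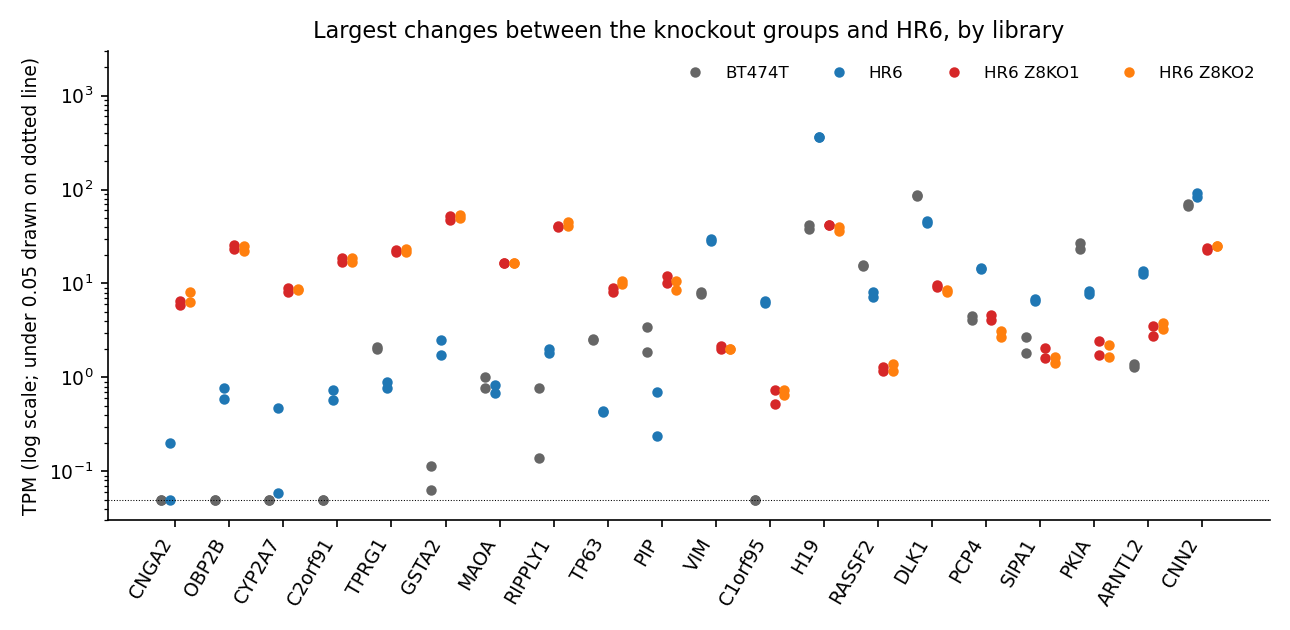
TPM (vertical log axis, values under 0.05 drawn on the dotted line) of the 10 genes that rose most and the 10 that fell most in the knockout groups among called genes with a mean of at least 5 TPM in the higher group and no overlap between libraries, 1 point per library and 1 colour per group. TP63 lies at 0.433 TPM on average in HR6 against 8.52 and 10.2 TPM in Z8KO1 and Z8KO2, and VIM at 29.1 against 2.09 and 2.02 TPM.

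Among called genes with a mean of at least 5 TPM in the higher group and no overlap between libraries, the others that rose most were the olfactory channel subunit CNGA2 (5.70 ± 0.30), the odorant-binding protein OBP2B (5.08 ± 0.29), the cytochrome CYP2A7 (4.97 ± 0.28), C2orf91 (4.74 ± 0.15), TPRG1 (4.73 ± 0.13), the glutathione transferase GSTA2 (4.56 ± 0.14), monoamine oxidase MAOA (4.44 ± 0.12), RIPPLY1 (4.41 ± 0.16) and the apocrine marker PIP (4.38 ± 0.45). TPRG1 and TP63 are neighbours in the RefSeq gene order of GRCh38.p14. OBP2B, CYP2A7 and GSTA2 have close paralogs that could share their reads. By the same rule, the others that fell most were C1orf95 (-3.28 ± 0.13), the RAS effector RASSF2 (-2.62 ± 0.11), the imprinted NOTCH ligand relative DLK1 (-2.35 ± 0.08), PCP4 (-2.03 ± 0.23), SIPA1 (-2.02 ± 0.14), PKIA (-2.01 ± 0.12), the clock factor ARNTL2 (-2.01 ± 0.08) and calponin CNN2 (-1.87 ± 0.05).

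Camera called 15 of 31 lists and none with an estimated correlation, where the lowest adjusted p was 0.0682. Acute-phase and secreted defence genes rose in 9 of 12 and fell in 1 (median 1.20, camera adjusted p = 1.2e-09; adjusted p = 0.0682 with an estimated correlation). Beside LCN2, the airway protein BPIFB1 rose from 145 to 673 and 676 TPM (2.20 ± 0.03), PIGR by 4.05 ± 0.46, and the protease inhibitor SERPINA3 was 14.9-fold higher (counting interval 4.93 to 73.6). Basal keratins and squamous genes rose in 9 of 10 and fell in none (median 1.34, camera adjusted p = 3.5e-06; adjusted p = 0.102 with an estimated correlation). Another 9 members in the table were not tested, among them KRT5, KRT14, KRT17, KRT6A and KRT6B, which had at most 16 counts in any library. Among those tested, involucrin IVL was 15-fold higher (counting interval 3.97 to 127), KRT16 rose by 2.37 ± 0.52 and S100A2 by 2.18 ± 0.21. Androgen response and apocrine genes rose in 12 of 18 and fell in 3, or 13 and 3 adjusted over the list alone (camera adjusted p = 2.2e-09; adjusted p = 0.0682 with an estimated correlation), with PIP, ACSM3 (2.64 ± 0.18), CYP4X1 (2.52 ± 0.10) and the steroid-conjugating UGT2B28 (2.04 ± 0.61). Drug efflux transporters and mucins rose in 9 of 14 and fell in 2, or 9 and 4 adjusted over the list alone (camera adjusted p = 2.3e-07; adjusted p = 0.102 with an estimated correlation). The transporters ABCC12 (3.27 ± 0.16), ABCC11 (2.38 ± 0.05) and ABCC2 (2.03 ± 0.05) rose, whereas ABCC4 fell (-1.79 ± 0.10).

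Estrogen receptor targets rose in 15 of 28 and fell in 5 (camera adjusted p = 0.012; adjusted p = 0.112 with an estimated correlation), led by SERPINA1 (2.60 ± 0.05), PDZK1 (1.49 ± 0.63) and OLFM1 (1.24 ± 0.26) with CXCL12 lower (-1.87 ± 0.27). ESR1 itself changed by 0.15 ± 0.04 and PGR was not called (-0.04 ± 0.09, edgeR adjusted p = 0.72). Luminal and epithelial identity genes rose in 10 of 22 and fell in 6 (median 0.01, camera adjusted p = 0.023; adjusted p = 0.326 with an estimated correlation), with PROM1 at 2.25 ± 0.05 and GATA3 at 1.36 ± 0.09. Mesenchymal genes fell in 7 of 23 and rose in 4 (camera adjusted p = 0.016; adjusted p = 0.229 with an estimated correlation). Beside VIM, the matrix protein THBS1 fell (-1.15 ± 0.04), and the matrix protein SPARC (2.97 ± 0.38) and TGFB2 (1.27 ± 0.40) rose from under 0.2 TPM. Camera on limma's log2(TPM + 1) values, a setting chosen after the data were seen, no longer called the luminal, mesenchymal, 17q12 or endothelial lists. Camera with the replicate number as a block lost the luminal, mesenchymal and 17q12 lists, and on quantile-normalized values it lost these, the endothelial list and that of ZMYND8 and its partners. Cholesterol synthesis genes fell in 16 of 24 and rose in 3 (camera adjusted p = 0.0032; adjusted p = 0.112 with an estimated correlation), with the sterol carrier STARD4 at -1.01 ± 0.09 and lanosterol synthase LSS at -0.50 ± 0.04. Members of the list of ZMYND8 and its reported chromatin partners fell in 19 of 31 and rose in 4, or 20 and 5 adjusted over the list alone (median -0.11, camera adjusted p = 0.012; adjusted p = 0.112 with an estimated correlation). The remodeller subunits CHD3 (-0.33 ± 0.03) and MTA2 (-0.32 ± 0.03) fell and ZNF532 rose (0.66 ± 0.04).

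Mitotic genes rose in 16 of 28 and fell in 3, or 17 and 3 adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.365 with an estimated correlation), by small amounts such as HMMR at 0.51 ± 0.08 and the centrosomal kinase NEK2 at 0.49 ± 0.07. DNA replication genes fell in 17 of 35 and rose in 1 (camera adjusted p = 0.023; adjusted p = 0.259 with an estimated correlation), with E2F2 at -0.43 ± 0.04 and GINS2 at -0.41 ± 0.06. Ribosomal proteins fell in 23 of 27 (median -0.17, camera adjusted p = 7.2e-05; adjusted p = 0.326 with an estimated correlation), with RPL7 at -0.55 ± 0.06 and RPL37A at -0.28 ± 0.03. Replication-dependent histones rose in 8 of 11 and fell in 1 (median 1.07, camera adjusted p = 3.3e-04; adjusted p = 0.102 with an estimated correlation), with HIST1H1C from 50.2 to 153 and 164 TPM (1.64 ± 0.07). Genes next to ERBB2 on 17q12 fell in 7 of 13 and rose in 3 (camera adjusted p = 0.023; adjusted p = 0.326 with an estimated correlation), with PPP1R1B at -0.52 ± 0.03, CDK12 at -0.46 ± 0.02 and TCAP higher at 0.61 ± 0.11. ERBB2 changed by -0.33 ± 0.02, ERBB3 by -0.39 ± 0.02 and EGFR by 0.15 ± 0.03. Endothelial markers rose in 4 of 5 and fell in none (camera adjusted p = 0.025; adjusted p = 0.257 with an estimated correlation). PECAM1 was at least 11-fold higher, at 0.497 and 0.508 TPM, CDH5 went from 8.74 to 17.1 and 17.3 TPM (0.96 ± 0.08), VWF rose by 1.31 ± 0.11 and ESAM by 0.38 ± 0.14. For 27 of 34 lists the counts were identical when adjusted over the list alone.

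**Figure D3:**
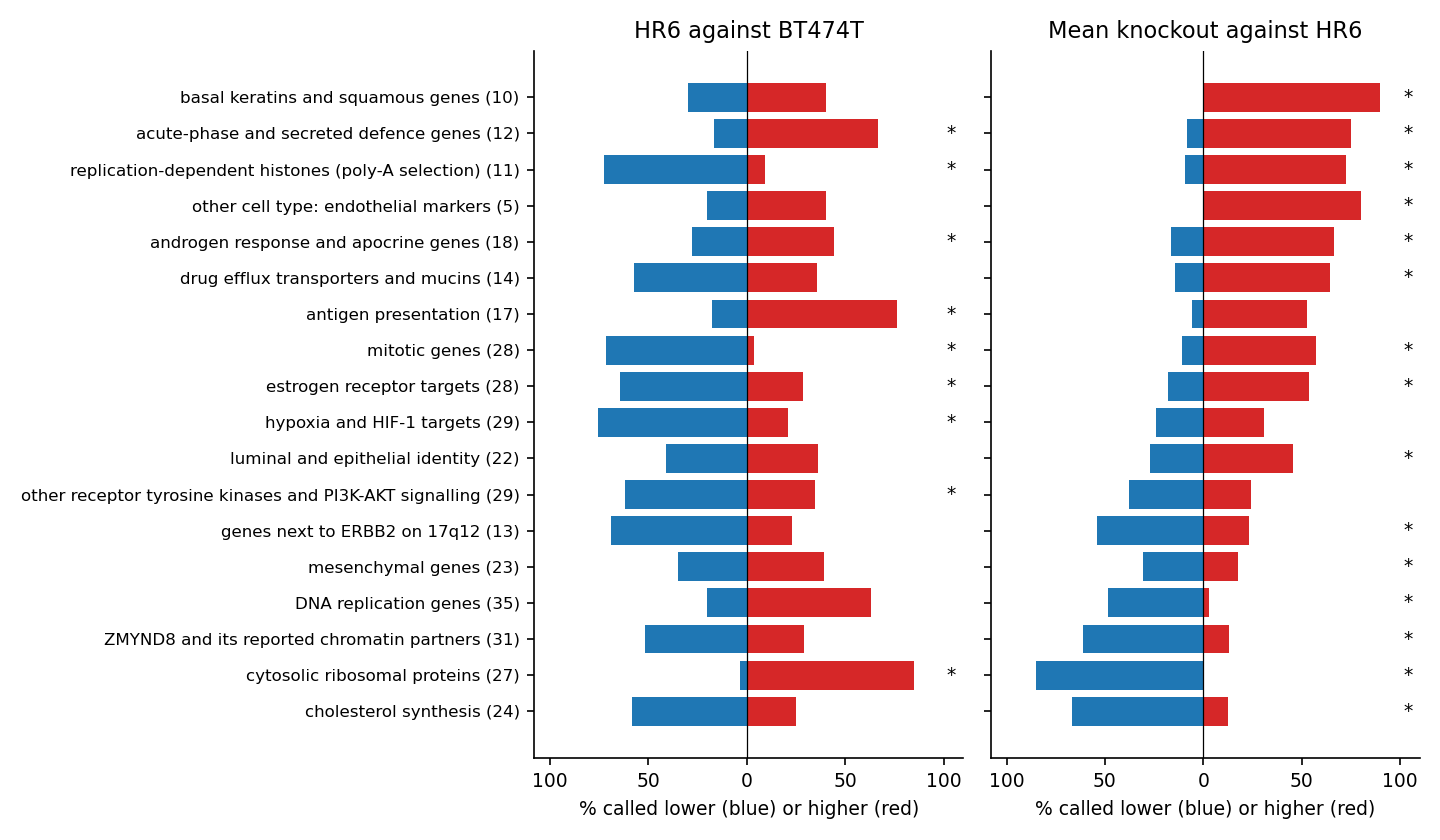
Percent of tested members called lower (blue, to the left) or higher (red, to the right) for the 18 lists that camera called in at least 1 comparison, with the number of tested members in parentheses and a star at a camera adjusted p under 0.05. Ribosomal proteins had 23 of 27 members higher in HR6 than in BT474T and 23 of 27 lower in the knockout groups than in HR6.

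The other 16 lists were not called by camera in the knockout comparison (adjusted p from 0.0529 to 0.783). NF-kB cytokines rose in 7 of 12 and fell in 2 (camera adjusted p = 0.0529), antigen presentation genes in 9 and 1 of 17 (camera adjusted p = 0.0695), and interferon-stimulated genes in 12 and 3 of 35 (camera adjusted p = 0.213). Genes higher and lower were 5 and 1 of 8 for DNA sensing (6 and 1 adjusted over the list alone), 7 and 1 of 16 for immediate early genes, 5 and 7 of 19 for stem cell markers, 4 and 7 of 27 for the unfolded protein response, 7 and 11 of 29 for receptor kinases and PI3K-AKT (9 and 12 adjusted over the list alone), 5 and 8 of 19 for IL-6 family and JAK-STAT3, and 9 and 7 of 29 for hypoxia. They were 4 and 3 of 8 for ERBB receptors and ligands, 5 and 3 of 13 for oxysterol genes, 1 and 2 of 5 for packaging cell markers, 3 and 2 of 22 for apoptosis, 7 and 8 of 20 for fatty acid synthesis, and 11 and 6 of 24 for p53 targets (11 and 7 adjusted over the list alone). Among members, CD44 rose from 36.1 to 152 and 168 TPM (2.13 ± 0.03), the chemokine CCL22 by 2.76 ± 0.09, the restriction factor BST2 by 2.55 ± 0.22, OAS1 by 1.20 ± 0.11, B2M by 0.67 ± 0.03, INPP4B by 2.12 ± 0.08, RET by 1.73 ± 0.07, EGR1 by 1.60 ± 0.08, the ligand EGF by 1.39 ± 0.10 and TMEM173 by 0.32 ± 0.07. The lipogenic factor THRSP was at least 12.9-fold higher. The pluripotency factor SOX2 (-2.62 ± 0.40), FGFR4 (-1.83 ± 0.04), FGFR3 (-1.43 ± 0.06), LIF (-1.67 ± 0.50), SOCS3 (-1.54 ± 0.22), the cholesterol exporter ABCA1 (-1.37 ± 0.11), galanin GAL (-1.36 ± 0.18), ERBB4 (-1.0 ± 0.09) and TRIB3 (-0.68 ± 0.03) fell. For the stem cell list the median was -0.11, the mean 0.02 and the camera direction up, for the oxysterol list 0.07, -0.01 and down, and for the ERBB list the mean was 0.09 and the direction down. Of lists with too few tested members, COL6A3 rose (1.77 ± 0.44) and COL1A1 fell (-0.56 ± 0.04), CD68 rose (1.84 ± 0.15), ITGAM was 8.63-fold higher (counting interval 2.21 to 74.2), CD8A (-0.83 ± 0.22) and CORO1A (-0.46 ± 0.08) fell, and MAGEC1 rose (1.79 ± 0.55). IL27, a cytokine subunit, had 5 counts in HR6, 21 in Z8KO1 and 13 in Z8KO2 and was not tested, nor was MB21D1 (cGAS), with 3, 1 and 2 counts.

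Each knockout group was also compared with HR6 on its own. Z8KO1 had 3446 genes higher and 3424 lower, and Z8KO2 had 2933 and 2972, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2457 were higher and 2467 lower in both groups, where independent lists would share 693 and 698, and 17 were called in opposite directions. Fold changes against HR6 correlated at 0.916 across genes. Unchanged groups simulated from the HR6 means gave a correlation of 0.498 and on average 0.05 genes called in both. The covariance was 0.390 against a simulated 0.0316, a difference of 0.359. With 1 HR6 library given to each knockout group, a split chosen after the result was seen, 1723 and 1777 genes were higher and lower in both (466 and 476 for independent lists), or 1847 and 1857 with the libraries exchanged (447 and 466). The covariance was then 0.376 and 0.377. Each comparison then rests on 1 HR6 library, and part of the excess in the joint fit may still come from the shared controls.

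The knockout groups differed directly in 759 genes, 416 higher and 343 lower in Z8KO2, of which 2 and 8 changed at least 2-fold. Scaled by library size alone, the split was 311 higher and 428 lower. ZMYND8 itself was higher in Z8KO2 than in Z8KO1 (0.23 ± 0.03, edgeR adjusted p = 8.3e-06). POTEE (0.72 ± 0.16), the diacylglycerol kinase DGKH (0.57 ± 0.13), RPL7 (0.55 ± 0.08), the kinase MAP3K8 (0.55 ± 0.15) and ANKRD36 (0.53 ± 0.10) were highest in Z8KO2 by the naming rule. RPPH1, the RNA of RNase P (-1.93 ± 0.29), ANKRD30BL (-1.39 ± 0.16), the transcription factor CEBPD (-0.71 ± 0.22), the chaperone subunit PFDN4 (-0.69 ± 0.09) and LYPLAL1 (-0.62 ± 0.13) were lowest. POTEE, ANKRD36 and RPL7 have near-identical copies that could share their reads. Of the 979 genes changed at least 2-fold in the mean knockout comparison, 16 differed between the knockout groups. The count of 759 depended on single libraries: it was 65 higher and 44 lower without Z8KO1 replicate 2, 91 and 54 without Z8KO2 replicate 2, 157 and 122 without Z8KO2 replicate 1, 176 and 181 without Z8KO1 replicate 1, 671 and 620 without BT474T replicate 1, and 600 and 656 without BT474T replicate 2. It was 6 higher and 9 lower with limma on log2(TPM + 1), a setting added after the data were seen.

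**Figure D4:**
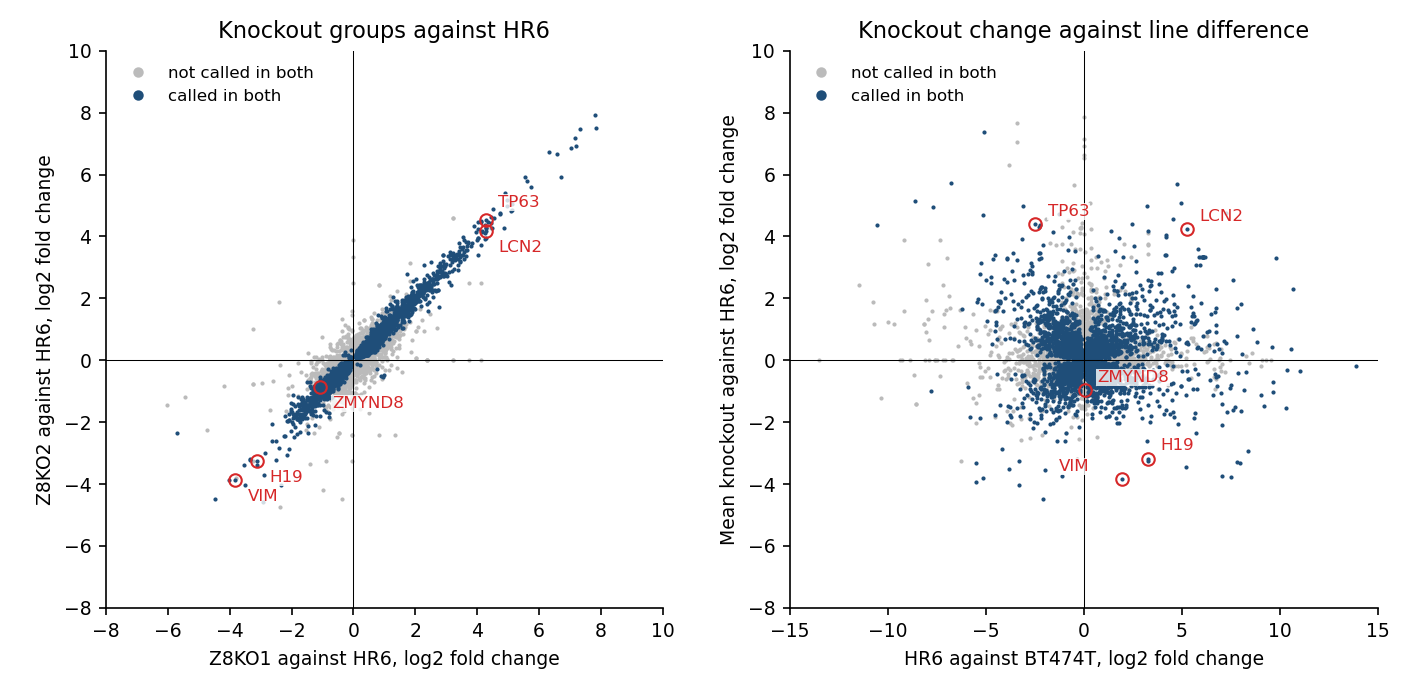
Log2 fold changes of each tested gene, with genes called in both comparisons in dark blue and others in grey: on the left Z8KO2 against HR6 (vertical) by Z8KO1 against HR6 (horizontal), on the right the mean knockout change (vertical) by the difference of HR6 from BT474T (horizontal). Points on the left follow the diagonal (correlation 0.916), those on the right do not (-0.027). Fitted values are drawn, which are not bounds for genes without counts in a group.

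The last comparison asked whether the knockout moved genes that separate HR6 from BT474T back toward BT474T. H19, higher in HR6 by 3.26 ± 0.05, and VIM, higher by 1.94 ± 0.10, both fell in the knockout groups, while LCN2, also higher in HR6, rose further. In all, 1690 genes were higher in HR6 and lower in the knockout groups (1350 for independent lists) and 1396 lower and then higher (1304 for independent lists), 3086 together. The same direction was seen in both comparisons for 1286 genes (1312 for independent lists) and 1265 genes (1343 for independent lists). Of the 2734 genes that differed at least 2-fold between HR6 and BT474T, 766 (28.0%) were called the opposite way in the knockout groups and 682 (24.9%) the same way. With 2-fold required in both comparisons, 89 genes were higher and then lower and 189 lower and then higher. By that rule 187 were higher in both and 94 lower in both, so opposite moves did not outnumber moves in the same direction. The number that independent lists would share was not computed for the 2-fold rule. Because HR6 enters both comparisons with opposite sign, unchanged groups simulated from the HR6 means gave a correlation of -0.614, and the observed one was -0.027. The covariance was -0.0230 against a simulated -0.0312, a difference of 0.0082. That simulation set every group to HR6 levels, and the split by HR6 library below gave covariances under 0, so the sign of the difference is not settled. With a separate HR6 library for each comparison, 1268 genes were higher and then lower (976 for independent lists) and 996 lower and then higher (937), or 1287 (1010) and 1038 (986) with the libraries exchanged, and the covariance was -0.0149 and -0.0123. Genes moved the same way numbered 974 higher (932 for independent lists) and 971 lower (982), or 1048 (983) and 1023 (1013) with the libraries exchanged. Part of the excess in the joint fit may come from the shared controls.

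Among genes higher in HR6 and lower after the knockout, the leading ones by the product of both fitted log2 fold changes, a rank that favours genes with few or no counts in a group, were the netrin receptor DCC (-3.77 ± 0.26 in the knockout comparison), the anion transporter SLC26A8 (-3.30 ± 0.41), C1orf95, FAM9C (-2.92 ± 0.33), LRRN3 (-3.46 ± 0.54), C1orf110 (-1.53 ± 0.14), SAMD5 (-2.10 ± 0.23) and TIMP3 (-1.49 ± 0.10). In the other direction, BANK1, a B cell adaptor, was 34.4-fold higher after the knockout (counting interval 11.6 to 168) and the arylamine acetyltransferase NAT2 32.0-fold (5.54 to 1.28e+03), and the receptor GPR26 rose by 3.15 ± 0.52. THRSP was at least 12.9-fold higher, WISP1 at least 4.06-fold, FBXO27 at least 2.71-fold, the interferon regulatory factor IRF8 at least 2.37-fold and DOK5 at least 1.52-fold, the last to 0.175 and 0.162 TPM against 13.6 TPM in BT474T.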

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

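The GC and length test, the sign test and the ZMYND8 neighbour test were chosen only after the result was seen, while the chromosome segment and imprinted gene tests were written down first.

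The first pattern was that 979 genes moved at least 2-fold in the mean knockout comparison. A gain or loss of chromosome segments shared by both knockout groups could do this. Of the placed genes, without chromosome X, 869 of 917 (94.8%) kept a 2-fold change after the median of 30 neighbours was subtracted. This argues against wide segments, but such a median cannot show changes of a few adjacent genes. GC content or length bias could also move these genes, yet 942 of 979 (96.2%) stayed called at 2-fold with that trend removed, which argues against such bias. Passage, selection or a guide-independent effect shared by both knockout groups and not by HR6 could also do it. The 979 genes were chosen on the mean of both groups, which nearly fixes 1 sign in both, so the 100% that shared it is no evidence and this stays open.

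The second pattern was ZMYND8 mRNA at 50.8% of the HR6 level in both knockout groups together. Loss of chromosome copies around ZMYND8 might lower it. The 20 nearest tested neighbours had a median of -0.16 with 12 of them lower, against an SD of 0.0877 for medians of 30 neighbours over all placed genes. Among these 20, CTSA (0.46), SLC13A3 (0.91), LOC100131496 (3.59) and PREX1 (0.25) were called higher. ZMYND8 lay 0.82 below the median of these 20 on the log2 scale, so loss of a segment spanning them is unlikely to be the whole cause. The 30 neighbours of TMEM189-UBE2V1, all on 1 side of ZMYND8, had a median of -0.27, which is 3.04 SDs below the median window. A partial loss on that side was not tested and stays open. Unedited cells among the knockout cells may also leave this level, and so may edited transcripts that escape decay, and whole-gene counts cannot tell these apart. The labels do not say whether the knockout groups are clones or pools, so differences between them may also come from founder cells.

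The third pattern was the near absence of SNRPN, SNURF, IPW and PAR5 in HR6. Loss of the chromosome segment could explain it, but the 10 nearest tested neighbours outside the cluster had a median of -0.0187, which argues against loss of a wide segment. If imprinted genes had changed as a class, more of them should move: 12 of 40 others (30%; 5 higher, 7 lower) changed at least 2-fold against 18.7% of other tested genes (Fisher exact two-sided p = 0.10, odds ratio 1.87, interval 0.863 to 3.79), so this stays open. H19, DLK1 and CDKN1C had been seen before and were left out of that test. MKRN3 belongs to the SNRPN cluster, and without it, a choice made after the result was seen, the count was 11 of 39 (28.2%, Fisher exact two-sided p = 0.147).

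The knockout groups differed from each other in 759 genes by edgeR. RPL7 was higher in Z8KO2 than in Z8KO1 by 0.55 (SE 0.08, edgeR adjusted p = 7.1e-06). TCAP was lower by edgeR at -0.39 (SE 0.12, adjusted p = 0.036), and HMMR at -0.34 (SE 0.09, adjusted p = 0.012). EGFR was higher by edgeR at 0.24 (SE 0.04, adjusted p = 1.9e-05), and so was ZMYND8 at 0.23 (SE 0.03, adjusted p = 8.3e-06). THBS1 was less reduced in Z8KO2 by edgeR, with a difference of 0.19 (SE 0.05, adjusted p = 0.011), as were CDK12 at 0.19 (SE 0.03, adjusted p = 3.4e-05) and CHD3 at 0.16 (SE 0.03, adjusted p = 6.1e-04). ZNF532 was more raised in Z8KO2 by edgeR, with a difference of 0.15 (SE 0.04, adjusted p = 0.020), as were ABCC2 at 0.14 (SE 0.04, adjusted p = 0.036) and CD44 at 0.14 (SE 0.03, adjusted p = 0.0043). RPL37A differed by edgeR at 0.11 (SE 0.03, adjusted p = 0.044) and ERBB3 at 0.10 (SE 0.03, adjusted p = 0.045).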

How the results depend on the processing

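Limma on log2(TPM + 1), library size scaling, thinning, GC and length removal, the crossed block and the HR6 split were chosen only after the result was seen. With 2 libraries per group and unstated replicate type, the p-values cover the spread between these libraries alone, and no setting can separate cell line history from resistance. Of up to 340 named gene values, 0 reversed direction among those called in the main fit or in the setting. A change of sign in values called in neither was not counted. Most named genes were picked for large fold changes among called genes in these same data. A reversal was therefore unlikely, and the 0 says little about smaller calls. DESeq2 kept 309 of 330 as they were and weakened 21, limma on log2(TPM + 1) kept 286 of 303, and leaving out HR6 replicate 2 weakened 18. Limma on quantile-normalized values weakened 23 of 303, and a required absolute log2 fold change of 1 weakened 101 of 340. A required absolute log2 fold change of 1 left 1402 genes higher and 1332 lower in HR6 against BT474T, 678 and 301 in the mean knockout comparison, 682 and 301 for Z8KO1, 659 and 296 for Z8KO2, 2 and 8 for Z8KO2 against Z8KO1, 787 genes shared by both knockout groups and 278 moved the opposite way. It also left 187 genes higher and 94 lower in both HR6 against BT474T and the mean knockout comparison. The comparison of Z8KO2 with Z8KO1 depended most on the setting, and the cause was not tested. Against 416 higher and 343 lower, it gave 274 and 106 with DESeq2 (which left 10745 of 14585 genes without an adjusted p), 6 and 9 with limma on log2(TPM + 1), 8 and 8 with a pseudocount of 0.1, 6 and 7 with a pseudocount of 5, 8 and 10 with quantile normalization, 3 and 6 without trend, 36 and 33 with robust variance, and 783 and 820 with only the compared groups. Limma without trend also gave 1971 genes lower in Z8KO2 against HR6. With 1 library left out it ranged from 65 to 671 higher and from 44 to 656 lower: 65 and 44 without Z8KO1 replicate 2, 91 and 54 without Z8KO2 replicate 2, 157 and 122 without Z8KO2 replicate 1, 176 and 181 without Z8KO1 replicate 1, 671 and 620 without BT474T replicate 1, and 656 lower without BT474T replicate 2. The other comparisons stayed within 1.5-fold when a library was left out. With the replicate number as a block, 5422 genes were higher and 5374 lower in HR6 against BT474T, and 3426 and 3519 in the mean knockout comparison. The crossed block gave 5563 and 5598 in HR6 against BT474T. Camera called 9 lists for HR6 against BT474T, 4 on limma values, 8 on quantile-normalized values (6 of the 9), 9 with the block and 0 with an estimated correlation, and fry called 27. For the mean knockout these were 15, 14 (11 of the 15), 11 (10 of the 15), 13 (12 of the 15), 0 and 27.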

Other observations

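Families of genes with a shared symbol stem were tested only after the result was seen, over 166 stems, and their members were chosen after their values were seen. No stem in either comparison passed camera with an estimated correlation. UGT genes, which add glucuronic acid, were higher in the knockout groups in 12 of 16 and lower in 1 (camera adjusted p = 1.1e-103; adjusted p = 0.101 with an estimated correlation). UGT1A1 went from 0.266 TPM in BT474T to 16.8 in HR6 and to 167 and 178 TPM in Z8KO1 and Z8KO2 (3.34 ± 0.06 over HR6), but the 9 UGT1A symbols share exons and amount to 1 measurement, which shrinks that p. Aldo-keto reductases rose in 6 of 10 and fell in none (camera adjusted p = 4.1e-13; adjusted p = 0.101 with an estimated correlation). AKR1B10, which reduces retinal, went from 2.69 TPM in BT474T to 35 TPM in HR6 and to 246 and 256 TPM (2.83 ± 0.05), and AKR1B1 rose from 1.73 TPM in HR6 to 31.3 and 31.5 TPM (4.16 ± 0.16). Cytochromes P450 rose in 14 of 29 and fell in 1 (camera adjusted p = 2.5e-05; adjusted p = 0.301 with an estimated correlation), such as CYP4B1 from 38.0 to 149 and 157 TPM (2.0 ± 0.05). ABCC transporters rose in 6 of 10 and fell in 1 (camera adjusted p = 3.3e-08; adjusted p = 0.509 with an estimated correlation). The glutathione transferase GSTA3 went from 0.384 TPM in BT474T to 41.9 TPM in HR6 (6.89 ± 0.24).

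Claudins, which seal tight junctions, rose in the knockout groups in 9 of 11 and fell in none (camera adjusted p = 6.5e-05; adjusted p = 0.788 with an estimated correlation), with CLDN2 from 24.4 to 144 and 151 TPM (2.58 ± 0.04). SOX transcription factors fell in 9 of 11 and rose in none (camera adjusted p = 0.0013; adjusted p = 0.788 with an estimated correlation), with SOX6 at -1.48 ± 0.13 and SOX11 at -0.55 ± 0.04. Zinc finger genes fell in 162 of 460 and rose in 31, which camera did not call (adjusted p = 0.058). In HR6 against BT474T, HOXB genes rose in 8 of 10 and fell in 1 (camera adjusted p = 1.7e-05; adjusted p = 0.972 with an estimated correlation), with HOXB3 at 6.31 ± 0.11, HOXB4 at 4.22 ± 0.15 and HOXB8 lower at -3.41 ± 0.44. All 13 PCDHA protocadherins were higher in HR6, but they share exons.

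Imprinted genes other than SNRPN moved in both directions. PEG10 went from 632 TPM in BT474T to 40 TPM in HR6 (-3.91 ± 0.03) and back to 223 and 243 TPM in the knockout groups, and its neighbour SGCE followed (-3.72 ± 0.13, then 2.14 ± 0.15). RASGRF1 changed by -1.43 ± 0.15 and then 1.52 ± 0.14, and MEG3 fell in HR6 by 1.78 ± 0.15. MKRN3, from the SNRPN cluster, was at least 63.4-fold higher in HR6, while UBE3A was lower (-0.79 ± 0.04).

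The HIST1 cluster of replication-dependent histones had 18 of 21 genes lower and 1 higher in HR6 (median -1.60), and 13 higher and 1 lower in the knockout groups (median 1.07). A copy change of the segment could move these genes, but the 13 other genes among them had medians of -0.02 and -0.16, so it is an unlikely cause. Because this kit selects poly-A tails, a shift in polyadenylated histone transcripts remains possible and was not tested.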
